A study of Mus musculus with 2 samples.

How the data were processed

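A pair of single-cell libraries were compared, 1 from subcutaneous 4T1 tumours of mice given phototherapy with AIE COF, a covalent organic framework preparation, and 1 from tumours of mice given PBS. Per the labels' protocols, tumours were collected on day 7 after phototherapy, made into cell suspensions, prepared with the MobiCube 3' kit of MobiDrop and sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, STAR and the mm10 build were used; their versions, the counting program and its gene annotation are not given in the sources used here. The labels name the mouse strain as C57BL/c, which is not resolved here. The values the authors deposited are whole UMI counts per gene and barcode, not normalized, for 32285 genes in each library. The lowest barcode total was 500 UMIs in both libraries, so barcodes below that total are not analysed here. How many animals or tumours entered each suspension is not given in the sources used here.

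Barcodes with at least 200 detected genes and at most 20% mitochondrial UMIs were retained. Doublet scores were computed per library with Scrublet as provided in scanpy 1.11.5, and the barcodes with the highest scores were removed at a rate of 0.8% per 1000 barcodes, which took 694 treated and 569 PBS barcodes. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours fed a Leiden clustering at resolution 1.0 on both libraries together, without integration. Cells of T-like and NK-like clusters were clustered again at resolution 1.0. That second resolution was chosen after a clustering at 0.5 had been seen, which gave a poorly supported innate lymphoid name.

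Marker genes of each cell type were fixed before the data were examined, as were the filters, the first clustering, the gene lists and the rule for named genes. The rule that turned markers into names was set after the clusters had been seen. A cluster took a name when over 50% of that type's detected markers, and at least 3, reached 25% of their highest cluster level and had a UMI in at least 5% of its cells. It stayed unnamed when more markers of another type stood among its 10 leading genes, or when its median UMI count was under the library median divided by 3 and no own marker led it. Unnamed clusters with under 100 CPM of Ptprc, the gene of the leukocyte antigen CD45, and a median of at least 10000 UMIs were called Ptprc-low. That class and the T-like subgroups were added as units of comparison after the clusters had been seen.

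With 1 library per group there is no test and no p-value. Shares of cells carry exact Clopper-Pearson 95% intervals, summed UMIs exact Poisson intervals, and ratios exact conditional binomial intervals, and all of these cover counting error only. UMIs were summed per library over all retained cells and within each class of at least 100 cells in each library, and expressed as CPM of that sum. A gene at 0 UMIs was given a floor of 3 counts. Median log2 ratios over all genes with at least 50 UMIs lay between -0.0039 and 0.0316 in the 8 units compared.

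Each of 40 gene lists was summarised by the median log2 ratio of its members with at least 50 UMIs, where at least 5 were measured. That median was placed among 10000 random lists of equal size matched on mean expression, and a list stood apart at or below percentile 1 or at or above percentile 99. Members at least 1.5-fold higher or lower were counted. The named genes are 14 fixed genes, the 10 highest and 10 lowest ratios of the whole tumour at 50 CPM or more, and the 8 highest and 8 lowest of each class at 50 CPM or more with a UMI in at least 10% of cells and no other class of that library at 5 times the level. Mitochondrial, ribosomal, haemoglobin and unnamed genes were left out of that choice. In each list described in detail, the up to 4 measured members with the largest ratios are named. Which lists are described was settled after their values had been seen, the text leaves out some class genes, and 2 genes that the rule names are not reported here. A few other genes are named outside this rule as background levels or list members, having been chosen after their values were seen.

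Shares of cells with a UMI were computed after thinning every cell to 1000 UMIs and leaving out shallower cells. Gene positions come from GENCODE M21 on GRCm38, in which 32158 of the 32285 gene identifiers were found. Protein-coding genes that lie wholly inside another listed gene were at 0 in both libraries in 284 of 287 cases on the same strand and in 664 of 666 cases on the opposite strand, against 2072 of 14634 protein-coding genes without overlap. Values of genes that overlap a neighbour are therefore uncertain and can be too low.

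The statistics were tested on simulated data. With 15897 genes and whole-library totals, the intervals held the true value for 96.0% of genes simulated 2-fold apart and 97.0% of those 1.5-fold apart. With 6026 genes and sums the size of a small class, they held it for 94.0% in both cases. Of 200 lists without any shift, 1.5% stood apart at whole-library depth and 2.5% at small-class depth. The simulated genes varied independently and by counting error alone. These rates therefore do not cover lists of co-expressed genes or spread between libraries.

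Alternatives settled before the data were examined were other filters on cells, no removal of doublets, Leiden resolutions of 0.5 and 2.0, each library clustered on its own, scaling by the median ratio, equal weight for each cell or each class, thinning to 1000 UMIs, and list minimums of 10 or 200 UMIs. Added after seeing the data were shares among named immune cells, a minimum of 1000 UMIs, a thinned PBS library, lists in single Ptprc-low clusters, and lists without a cycling or an interferon-led T-like sub-cluster. The PBS library was thinned to 77.969% of its UMIs, the ratio of the B-like medians, so it was matched to the treated depth for B-like cells alone. The work used Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, with seed 1.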

Results

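Single-cell transcriptomes of subcutaneous tumours grown from 4T1, a mouse mammary carcinoma line, were compared between 1 library from mice given AIE COF phototherapy and 1 from mice given PBS. The series title names tertiary lymphoid structures, which are aggregates of B and T cells that form outside lymphoid organs, so lymphocytes were examined first. The treated library held 10002 barcodes and 115576457 UMIs and the PBS library 8962 barcodes and 145045294 UMIs. After filtering, 8619 treated and 7864 PBS cells remained, with medians of 3944 and 6412.5 UMIs and of 1648 and 2223 genes per cell. There are no replicates, so each difference below is between these libraries and has no replicate check.

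B-cell-like and T-cell-like cells made up larger shares of the treated library. B-like cells, led by Cd79a, Pax5 and Bank1, were 13.9% of treated cells (1200 cells, 95% interval 13.2 to 14.7%) and 4.63% of PBS cells (364 cells, 4.17 to 5.12%), a ratio of 3.01 (2.67 to 3.39). T-like cells were 18.1% (1561 cells) and 8.67% (682 cells), a ratio of 2.09 (1.91 to 2.29). Plasma-like cells, which secrete antibody, numbered 48 and 12, a ratio of 3.65 (1.91 to 7.55). NK-like cells were alike within counting error, at 1.13% and 1.21% (ratio 0.932, 0.695 to 1.25). Named immune cells were 55.2% of treated and 30.9% of PBS cells, so each log2 ratio is 0.84 lower when shares are taken among them, which gives 0.75 for B-like, 0.23 for T-like and -0.94 for NK-like cells. Named immune cells leave out the unnamed cluster 13, which carried Ptprc at 911 CPM and was 5.06% of treated and 9.13% of PBS cells.

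Among all kept cells, resting T cells were more frequent and CD8 effector cells less frequent in the treated library. Naive or central memory T-like cells, marked by the lymph node homing gene Ccr7, were 11.4% of treated cells (982 cells) and 2.90% of PBS cells (228 cells), a ratio of 3.93 (3.40 to 4.56). Follicular-helper-like T cells, named after the type that assists B cells, were 1.61% and 0.687%, a ratio of 2.35 (1.70 to 3.28). Their name rests on 5 markers met. After thinning to 1000 UMIs, Cxcr5, overlapped by Bcl9l at its end, was seen in 1 of 118 treated and 3 of 50 PBS cells of this subgroup. Pdcd1 was seen in 3 of 118 and 4 of 50. More cells able to assist B cells are therefore not shown. Regulatory-T-like cells numbered 123 and 79, a ratio of 1.42 (1.06 to 1.91), and their log2 ratio among named immune cells was -0.33. CD8-effector-like cells were 1.69% (146 cells) and 3.37% (265 cells), a ratio of 0.503 (0.408 to 0.618). Among T and NK cells the ratios were 2.02 (1.75 to 2.34) for naive-like, 1.21 (0.875 to 1.68) for follicular-helper-like, 0.730 (0.546 to 0.981) for regulatory-T-like and 0.258 (0.210 to 0.317) for CD8-effector-like cells. When each library was clustered on its own, the log2 ratio of CD8-effector-like cells turned to 0.49, that of naive-like T cells was 1.49 against 1.97, that of NK-like cells 1.45 against -0.10, and follicular-helper-like T cells had a name in the treated library alone. T and NK cells in sub-clusters without a name were 2.10% of treated and 0.852% of PBS cells.

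Myeloid classes differed less. Macrophage-like cells were 10.8% of treated and 8.33% of PBS cells (log2 ratio 0.38, 0.24 to 0.53) and monocyte-like cells 8.45% and 5.98% (log2 ratio 0.50, 0.33 to 0.67). Their log2 ratios among named immune cells were -0.46 and -0.34, and monocyte-like cells stood at -0.016 when the libraries were clustered apart, against 0.50. The unnamed cluster 13, which met 70.0% of the macrophage markers, was 5.06% of treated and 9.13% of PBS cells. Counted as macrophage-like, it would turn the higher treated share of that class into a lower one. Conventional-dendritic-like cells were 1.68% and 1.64%, with a log2 ratio of 0.036 that turned to -0.41 when the libraries were clustered apart and to -0.80 among named immune cells. Mature-dendritic-like cells, which carry Ccr7 and Fscn1, numbered 40 and 22 (ratio 1.66, 0.963 to 2.93). Fibroblast-like cells numbered 36 and 23, and endothelial-like cells 24 and 18, and clustering the libraries apart turned the fibroblast-like ratio below 1 and moved the endothelial-like log2 ratio to 1.48. No cluster met the rule for neutrophils.

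Cells with little Ptprc and much RNA were 30.1% of treated (2596 cells) and 38.1% of PBS cells (3000 cells), a ratio of 0.790 (0.749 to 0.832). They carried Hmga2 at 366 CPM and Rhox5 at 747 CPM but the epithelial gene Epcam at 0.462 CPM, so they are named by Ptprc alone. The class joins cluster 2, led by Cilp and H19 (793 treated and 1255 PBS cells), cluster 3 (567 and 765) and cluster 4 (1236 and 980), so the mix within it differs too. When the libraries were clustered apart, the log2 ratio of this class was 0.053, against -0.34. Unnamed clusters held 14.0% of treated and 30.4% of PBS cells. Clusters 0, 1 and 5, low in Ptprc but with fewer UMIs than the threshold, were 2.32% and 4.32%, 3.30% and 4.46%, and 3.01% and 12.4%, and the unnamed clusters 13 and 20 were 5.06% and 9.13%, and 0.348% and 0.0763%. Cluster 13 had Ptprc at 911 CPM and met 70.0% of the macrophage markers. A marker of another type among its leading genes kept it unnamed. The neutrophil genes S100a8 and S100a9 rank first in cluster 5 but had a UMI in 0.565% and 0.242% of its cells, and S100a8 had 1406 treated and 96 PBS UMIs in the libraries as a whole. The 500-UMI minimum and the difference in depth bear on all of these shares, since small lymphocytes lie near that minimum, with B-like medians of 1155.5 treated and 1482 PBS UMIs.

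**Figure D1:**
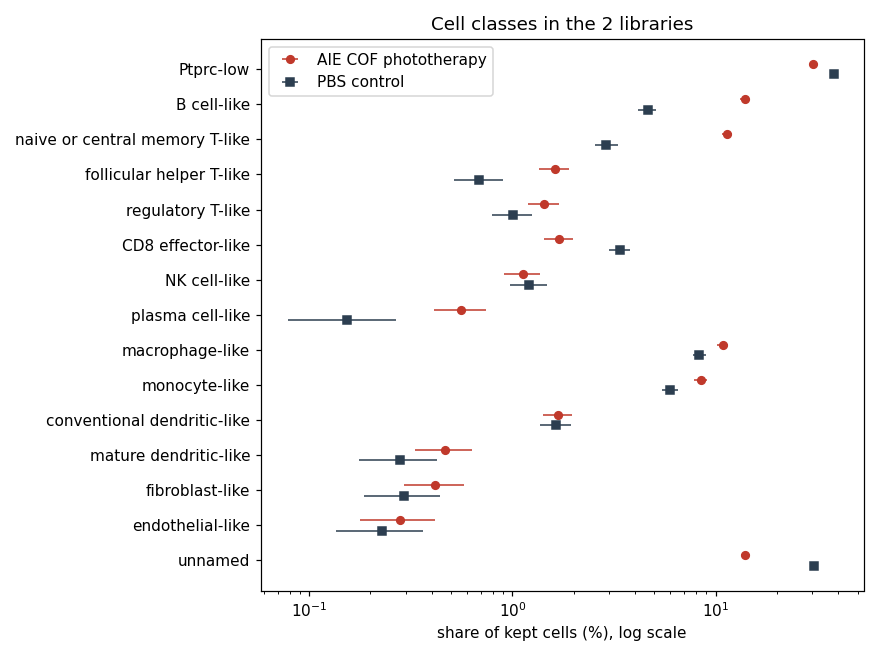
Share of retained cells in each class, in percent on a log axis, for the treated library (circles) and the PBS library (squares), with exact 95% binomial intervals that cover counting error only. B-like cells sit at 13.9% and 4.63%, and CD8-effector-like cells at 1.69% and 3.37%.

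In the whole tumour, Satb1 and Slpi had the highest ratios at 50 CPM or more. Satb1, a chromatin organiser of T cells on chromosome 17 (51736187 to 51833290, minus strand), was at 77.6 CPM (75.9 to 79.3) in the treated and 18.8 CPM (18.1 to 19.6) in the PBS library, 4.12-fold higher. The secreted protease inhibitor Slpi was 4.10-fold higher, the immunoglobulin heavy chain Ighg1 3.90-fold and the joining chain Jchain 3.78-fold. Equal class weight turned the log2 ratios of Ighg1 to -0.063 and of Jchain to -0.056, and that of Ubd, below, to 0.194. That weighting counts classes under 100 cells, such as plasma-like cells (48 treated and 12 PBS), as much as large ones. The cholesterol exporter Abca1 (2.82-fold), the chemokine Pf4 (2.74-fold), the phosphodiesterase Pde4b (2.70-fold), Cytip (2.64-fold), the neutrophil chemoattractant Cxcl2 (2.58-fold) and the lymphocyte repressor Bach2 (2.54-fold) followed. The lowest ratios were those of the imprinted RNA H19 (0.558), Dhx37 (0.585), Selenbp1 (0.588), Ubd (0.592), Tmem232 (0.600), the class I gene H2-Q4 (0.621), the linker histone Hist1h1e (0.627), Slc39a1 (0.634), Hist2h2ac (0.636) and the chaperone Dnajb1 (0.649). Another gene lies over the last 500 bases of Hist1h1e.

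Genes fixed for the question of lymphoid structures were mostly higher in the treated library. Cxcl13, the chemokine that draws B cells, had 39 treated and 18 PBS UMIs (log2 ratio 1.41, 0.57 to 2.30), and its receptor gene Cxcr5 418 and 232 (1.14, 0.91 to 1.38). Ccr7 stood at a log2 ratio of 1.61 (1.49 to 1.74), Cd79a at 1.42 (1.32 to 1.53), Cd4 at 0.94 (0.67 to 1.21), Lta at 0.76 (0.21 to 1.31) and Ltb at 0.54 (0.41 to 0.68). Cd3e was close to level at 0.18 (0.04 to 0.32), Cd8a was lower at -0.41 (-0.54 to -0.28), and Foxp3 had 56 UMIs in each library. Equal class weight turned Ccr7 (-0.55), Cd79a (-0.28), Cxcr5 (-0.095), Ltb (-0.43) and Cd3e (-0.69) negative, while Cd4 (0.69) and Lta (0.35) stayed positive. Small classes, such as mature-dendritic-like cells (40 treated and 22 PBS), can drive these values, so they do not show lower levels within the large classes. Ccl19, Ccl21a and Ms4a1 were listed at 0 in both libraries. Ccl19 and Ccl21a lie inside 4930578G10Rik on chromosome 4 and Ms4a1 inside 4930526L06Rik on chromosome 19, and other genes lie over the last 500 bases of Cxcr5 (Bcl9l) and Foxp3 (Ccdc22).

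Of 39 lists measured in the whole tumour, 22 stood apart as higher and 7 as lower in the treated library. B cell genes had a median log2 ratio of 1.42, with 10 of 11 measured members at least 1.5-fold higher, among them Fcmr (1.66), Bank1 (1.65) and Pax5 (1.64). Immunoglobulin and secretion genes stood at 1.44 with 8 of 10 higher, led by Ighg1, Mzb1, Jchain and Ighd. T cell genes stood at 0.56 with 7 of 14 higher, led by Bcl11b (1.38) and Cd28 (1.26), and naive and memory T cell genes at 1.26 with 8 of 10 higher, among them Satb1, Ccr7 and Il7r. The lymphotoxin and homing axis stood at 0.54 with 7 of 15 higher. Weighting each class equally turned the medians of B cell genes to -0.057, of immunoglobulin genes to -0.060, of T cell genes to -0.28 and of the lymphotoxin and homing axis to -0.095, and left 9 lists apart.

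Other whole-tumour lists concerned chemokines, cytotoxicity and myeloid cells. Tertiary lymphoid structure chemokines had a median of 0.66 (percentile 99.98) with 4 of 7 measured members higher, namely Cxcl13, Cxcl12 (0.88), Cxcl9 (0.72) and Ccl8 (0.66). That call ended when each cell had equal weight (0.095, Cxcl12 at -0.17), when cells were thinned (0.027) and under equal class weight (0.22). Cytotoxicity genes stood at -0.40 with 5 of 12 lower, including perforin Prf1 (-0.90) and the granzymes Gzmc (-0.88), Gzmk (-0.76) and Gzmb (-0.75). Alternatively activated macrophage genes stood at 0.81 with 9 of 15 higher, led by Ccl17 (1.99), Chil3 (1.34), Mrc1 (1.32) and Clec10a (1.15), a call that ended at 0.31 under equal class weight; in macrophage-like cells the list stood at 0.16 and in monocyte-like cells at -0.081, neither apart. Inflammatory macrophage genes (0.72, 6 of 11 higher), suppressive myeloid genes (0.70) and complement (0.59) were higher in the whole tumour too, so no polarisation is shown. The list of immediate early genes linked to tissue dissociation was also higher (0.40), with Nr4a1 at 0.97 and Dusp1 at 0.91. High endothelial venule genes (0.023, 5 of 11 members measured) and the cell cycle (0.069) did not stand apart. Glycam1, with 6 treated and 18 PBS UMIs, and Madcam1, with 10 and 6, were under the UMI minimum for any list. Endothelial-like cells numbered only 24 and 18. Whether high endothelial venules differ between the libraries therefore cannot be read from this median.

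**Figure D2:**
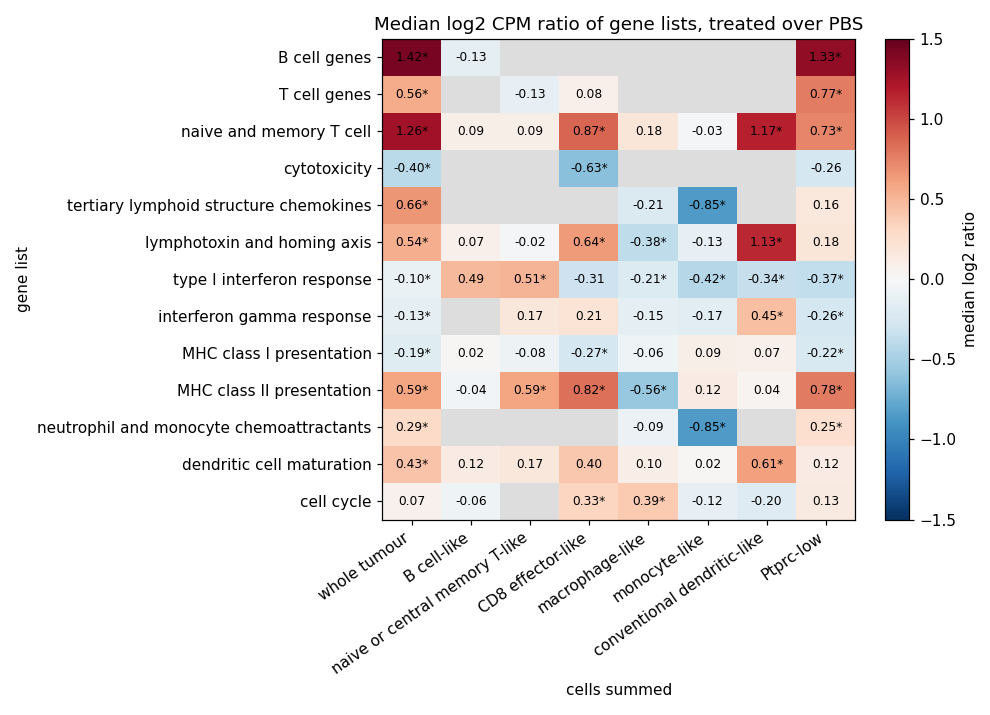
Median log2 ratio of CPM, treated over PBS, for 13 gene lists (vertical axis) in the whole tumour and 7 cell classes (horizontal axis). Colour and number give the median, a star marks a percentile at or below 1 or at or above 99, and grey marks fewer than 5 measured members. B cell genes read 1.42 in the whole tumour and -0.13 in B-like cells.

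Within B-like cells 1 of 23 gene lists stood apart, against 6 without doublet removal, 4 with equal cell weight and 3 with members of 10 UMIs or more. Oxidative stress genes had a median of -0.29 (percentile 0.54, 2 of 9 measured members lower and 1 higher), with the metallothionein Mt1 at -0.71, the lipid peroxidase Gpx4 at -0.70, Txnrd1 at -0.51 and Gclc, an enzyme of glutathione synthesis, at 0.95, and the call ended when cells were thinned and when doublets were left in. B cell genes stood at -0.13 and immunoglobulin genes at -0.053, neither apart. The highest ratios were those of Adgrd1 (2.69-fold), Tecpr2 (2.05-fold), Tor1aip2 (1.84-fold) and Ap1s3 (1.84-fold), and the lowest those of Atp5k (0.556), Snd1 (0.559), the phosphatase Ptpn6 (0.576) and Kpna3 (0.576). Adgrd1 had 230 treated and 32 PBS UMIs in this class (log2 1.43, 0.89 to 2.01).

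In naive-like T cells the type I interferon list stood apart as higher in the treated library, a call that several alternatives ended. The type I interferon list had a median log2 ratio of 0.51 (percentile 99.74), led by Oasl2 (1.35, 0.03 to 3.04), Irf7 (0.91, -0.17 to 2.20), Ifit1 (0.86, -0.23 to 2.14) and Ifit3 (0.77, -0.09 to 1.74), with 4 of 11 measured members at least 1.5-fold higher. Without a sub-cluster led by Ifi206 and Ifi203, which held 38 treated and 3 PBS cells, the median was 0.14 and the list no longer stood apart. The call also ended under the stricter cell filter (0.20), after thinning (0.46) and with members of 10 UMIs or more (0.29). Oasl2, Irf7, Ifit1 and Ifit3 had between 5 and 13 PBS UMIs. The immediate early genes linked to tissue dissociation were also higher in this class (0.29, percentile 99.95, 1 of 12 at least 1.5-fold), a call that ended after thinning (0.26). Single genes with the highest ratios were Letm1 (3.27-fold), Tecpr2 (2.63-fold) and Ubr2 (2.49-fold), and those with the lowest Ddt (0.385), Il27ra (0.411) and Soat1 (0.417).

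Fewer treated T-like cells had a UMI of the killing enzyme Gzmb, and the make-up of this class differs between the libraries, with 1160 treated and 294 PBS cells in cluster 8 but 117 and 244 in cluster 9, of which Gzmb is a leading gene. After thinning, 6.85% of 1329 treated and 26.0% of 634 PBS T-like cells had a Gzmb UMI (unthinned 8.52% and 34.0%; 232 and 48 cells dropped). In B-like cells, which should lack it, 0 of 780 treated cells (up to 0.472%) and 0.660% of 303 PBS cells did, at median depths of 1155.5 and 1482 UMIs against 1626 and 2501.5 in T-like cells. Within subgroups it was seen in 33.6% of 140 and 48.8% of 252 CD8-effector-like cells (unthinned 46.6% and 65.7%; 6 and 13 dropped), 34.3% of 108 and 55.6% of 72 regulatory-T-like cells (unthinned 39.0% and 64.6%; 15 and 7 dropped), and 0.124% of 806 and 1.48% of 203 naive-like cells (unthinned 0.204% and 1.32%; 176 and 25 dropped). Ccr7 was seen in 23.4% and 14.7% of thinned T-like cells (unthinned 33.6% and 22.7%), and in 0.279% and 0.214% of monocyte-like cells, whose medians were 4600 and 5334 UMIs.

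In CD8-effector-like cells the cytotoxicity list stood apart as lower in the treated library, a call that ended without a cycling sub-cluster. Cytotoxicity genes stood at -0.63 (percentile 0.0) with 6 of 11 lower, led by Gzmk (-1.68, -3.08 to -0.53), Prf1 (-1.23, -1.84 to -0.67), Ctsw (-0.97, overlapped by Fibp at its end) and Gzmc (-0.86). Naive and memory genes stood at 0.87 with 8 of 9 higher, among them S1pr1 (1.37), Bach2 (0.95) and Tcf7 (0.92), and cell cycle genes at 0.33 with 3 of 20 higher, led by Aurkb (0.90) and Cdk1 (0.79). The class joins sub-cluster 4, with 90 treated and 207 PBS cells, and the cycling sub-cluster 9, with 56 and 58, and Gzmb, Gzmk, Prf1, Nkg7 and Ifng are among its markers. Without sub-cluster 9 the cytotoxicity median was -0.20 and the cell cycle median 0.24, neither of them apart. The memory list could not be measured without it, and S1pr1 then kept 0 of 52 UMIs, Tcf7 12 of 79, Lef1 12 of 131, Bach2 75 of 204, Klf2 119 of 309, Satb1 188 of 390, Ccr7 33 of 68 and Il7r 155 of 254, so whether memory genes are higher outside sub-cluster 9 is not known. Single genes with the highest ratios were Gpm6b (3.86-fold), the transcription factor Maf (3.76-fold), Rasa3 (3.73-fold) and Areg (3.39-fold), and those with the lowest Ppp1r3b (0.259), Styk1 (0.283), Ifi214 (0.318) and the survival gene Bcl2 (0.329). Gpm6b is also among the leading genes of the follicular-helper-like and Areg of the regulatory-T-like sub-cluster, and after thinning 35.7% of 140 treated and 50.8% of 252 PBS cells of this class had a Cd8a UMI (unthinned 67.8% and 81.9%; 6 and 13 cells dropped). A different mix of T cell types within the class is therefore not excluded for these genes.

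In macrophage-like cells the class II list stood apart as lower and the cell cycle list as higher in the treated library. Class II presentation genes stood at -0.56 (percentile 0.0) with 4 of 8 lower, with the invariant chain Cd74 at -0.92 (2693 against 5080 CPM), H2-Ab1 at -0.73, H2-Eb1 at -0.64 and H2-DMa at -0.60. The class joins cluster 12, with 849 treated and 572 PBS cells, and cluster 16, with 86 and 83. Cd74 and H2-DMb1 are among the leading genes of cluster 16. The class II list was not measured in cluster 12 alone, so a different mix within the class is not excluded. Cell cycle genes stood at 0.39 with 2 of 20 at least 1.5-fold higher, led by Ccnb1 (0.61), Ccnb2 (0.60), Cenpf (0.56) and Mcm2 (0.56). Mitochondrially encoded genes were lower in this class too (-0.17, 2 of 13 lower). The type I interferon list stood at -0.21 (percentile 0.16, 0 of 18 lower by 1.5-fold), with Isg15 at -0.56 and Usp18 at -0.47 but Rsad2 at 0.35, which turned to -0.37 without doublet removal, and the list's call ended when cells were thinned (-0.028). Highest in ratio were the ubiquitin ligase Fbxo32 (2.28-fold), Ing3 (2.25-fold), Letm1 (2.24-fold), Emp1 (2.21-fold) and the cystine transporter Slc7a11 (2.19-fold), and lowest the heat shock gene Hspa1b (0.286), Clec4b1 (0.383), Klra17 (0.391) and Hspa1a (0.404).

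In monocyte-like cells the chemoattractant and type I interferon lists stood apart as lower in the treated library, the former not under every alternative. Neutrophil and monocyte chemoattractants stood at -0.85 (percentile 0.0), with Ccl12 at -0.92, Ccl7 at -0.90, Ccl3 at -0.88 and Ccl4 at -0.85, and 4 of 7 measured members lower and 1 higher. Without doublet removal that median was -0.083 and Ccl7 stood at 0.055, and with members of 10 UMIs or more it was -0.14, and the list did not stand apart in either case. Tertiary lymphoid structure chemokines, higher in the whole tumour, were lower here (-0.85, percentile 0.0), with Ccl5 at -0.92, Ccl3 at -0.88 and Ccl4 at -0.85 but Cxcl9 at 0.56, and stood at -0.21 in macrophage-like cells, not apart. That list shares Ccl2, Ccl3 and Ccl4 with the chemoattractant list, so these calls are not independent. The type I interferon list stood at -0.42 (percentile 0.0) with 6 of 18 lower, led by Usp18 (-0.77), Isg15 (-0.76), Oasl1 (-0.71) and Ifit3b (-0.68). Higher in the treated library were Nrg1 (2.25-fold), Adgrd1 (2.24-fold), the nuclear receptor Nr4a2 (2.18-fold) and the matrix protein Thbs1 (2.15-fold), and lower were Hspa1b (0.356), Hdac9 (0.383), Rnd3 (0.434) and Adap2 (0.507).

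In conventional-dendritic-like cells the maturation and interferon gamma lists stood apart as higher and the type I interferon list as lower in the treated library. The maturation list stood at 0.61 (percentile 99.99) with 5 of 9 higher, led by Il12b, a subunit of interleukin 12 (236 and 28 UMIs, 7.58-fold, log2 2.92, 2.35 to 3.54), Ccr7 (1.55), Cd80 (0.75) and Relb (0.69). With members of at least 200 UMIs it was 0.32 and did not stand apart, and after thinning too few members were left to measure it. Il12b and Ccr7 are also among the leading genes of the mature-dendritic-like cluster, and naive and memory T cell genes were higher in this class (1.17, 4 of 6), so mature or mixed cells within it are not excluded. Interferon gamma response genes stood at 0.45 with 4 of 9 higher, a call that ended with equal cell weight (0.22). The type I interferon list stood at -0.34 (percentile 0.02) with 6 of 17 lower, with Ifit3b at -1.61, Ifit2 at -1.27, Ifit3 at -1.02 and Ifit1 at -1.02, a call that ended when cells were thinned (-0.28). High ratios were also seen for the immediate early factor Egr2 (5.03-fold), the interferon-induced chemokine Cxcl9 (4.51-fold) and Zc3h12c (3.83-fold), and low ones for Hist1h2bc (0.159) and Hspa1a (0.180).

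In Ptprc-low cells the interferon and class I lists stood apart as lower in the treated library, few members by 1.5-fold. The type I interferon list stood at -0.37 (percentile 0.0) with 5 of 18 lower by that much, with Isg15 at -0.78, Zbp1 at -0.76, Ifi27l2a at -0.70 and Ifit3b at -0.63. Interferon gamma response genes stood at -0.26 (percentile 0.0, 2 of 15), with Gbp6 at -0.71, Irgm2 at -0.61, Iigp1 at -0.52 and Gbp5 at -0.52, and class I presentation genes at -0.22 (percentile 0.01, 0 of 10), with the class I regulator Nlrc5 at -0.39, Psmb9 at -0.35 and H2-D1 at -0.26. In cluster 4 alone the interferon gamma median was -0.002, and in cluster 3 alone the class I median was -0.12, neither apart. The chemokine Cxcl1 was 2.43-fold higher, Ddah1 2.23-fold, Adgrd1 2.18-fold, Naaladl2 2.16-fold and Tecpr2 2.01-fold. H2-Q4 (0.613), Dnajb1 (0.616), H19 (0.621) and Ubd (0.628) had the lowest ratios. H19 is a leading gene of cluster 2, which was 30.5% of treated and 41.8% of PBS cells of this class. For H19 the mix of clusters is therefore not told apart from a change within them.

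Lymphocyte lists also stood apart in Ptprc-low cells, B cell genes at 1.33, immunoglobulin genes at 1.39 and T cell genes at 0.77. Cd79a was at 1.83 CPM in Ptprc-low, 3.33 in macrophage-like and 1249 in B-like cells, and Cd3e at 0.849 in Ptprc-low, 0.983 in macrophage-like and 274 in T-like cells. Cd74 stood at 46.1 and 26.8 CPM in Ptprc-low and at 76.8 and 56.8 CPM in naive-like T cells of the treated and PBS library, against 8841 and 11042 CPM in B-like cells.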

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

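Medians of the same gene list were set side by side across cell classes, a comparison of directions chosen after the medians were seen. A list is given here when it stood apart as higher in 1 class and as lower in another. The differences between classes were not tested, and each value is a median log2 ratio of the treated over the PBS library. Interferon-stimulated genes of the type I list stood at 0.51 in naive-like T cells but at -0.21 in macrophage-like, -0.42 in monocyte-like, -0.34 in conventional-dendritic-like and -0.37 in Ptprc-low cells. The naive-like T call ended without 1 sub-cluster (0.14), and the macrophage-like and conventional-dendritic-like calls after thinning (-0.028 and -0.28). Interferon gamma response genes stood at 0.45 in conventional-dendritic-like and -0.26 in Ptprc-low cells, calls that ended with equal cell weight (0.22) and in cluster 4 alone (-0.002). Class II presentation genes stood at -0.56 in macrophage-like cells and at 0.59 in naive-like T, 0.82 in CD8-effector-like and 0.78 in Ptprc-low cells, classes in which Cd74 lies far below its B-like level; the naive-like T call ended without doublet removal (0.22) and the CD8-effector-like call with equal cell weight (0.55). Inflammatory cytokines stood at -0.48 in monocyte-like and 0.61 in Ptprc-low cells, and neutrophil and monocyte chemoattractants at -0.85 and 0.25 in the same classes. Without doublet removal the monocyte-like calls ended (-0.33 and -0.083), and in cluster 4 alone the Ptprc-low calls (0.24 and 0.22). The lymphotoxin and homing axis stood at 0.64 in CD8-effector-like, 1.13 in conventional-dendritic-like and -0.38 in macrophage-like cells, the last ending without doublet removal (-0.059), while too few members were left to measure the others after thinning. Nor could the CD8-effector-like values of this list and of class II be measured without the cycling sub-cluster. Oxidative stress genes stood at -0.29 in B-like and 0.16 in Ptprc-low cells, and these calls ended after thinning and with equal cell weight (0.13).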

How the results depend on the processing

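Shares among named immune cells, cells of at least 1000 UMIs, the thinned PBS library, single Ptprc-low clusters and the removal of a cycling or an interferon-led sub-cluster were chosen after seeing the data. Of 138 alternative values for class shares, 106 were the same, 26 moved and 6 reversed. Of 718 for list medians, 563 kept their call, 10 were stronger, 124 weaker and 21 reversed. Of 1120 for named genes, 883 were the same, 223 moved and 14 reversed, and for all 37 shares of cells with a UMI the ratio without thinning lay within the 95% interval of the thinned ratio. Shares and genes count as the same within the 95% interval of the reported value, and numbers of lists within 1.5 times it. Reversed is kept for a sign turned where that interval excludes a ratio of 1, so conventional-dendritic-like and fibroblast-like cells count as moved, or for a list that lost its call and turned sign. Scaling by the median ratio moves all genes of a unit alike by at most 0.0316 and gave 216 of the 883 and 94 of the 563, which therefore carry little weight. The thinned PBS library, in which cells kept their class, gave 16 of the 106, and these carry little weight too. Values below are log2 ratios or numbers of lists, and except where a reason is given the cause was not tested.

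Among named immune cells, whose own share differs, ratios were 0.752 for B-like, -0.939 for NK-like, -0.455 for macrophage-like, -0.338 for monocyte-like, 1.138 for naive-like T, -0.330 for regulatory-T-like and -1.829 for CD8-effector-like cells. With at least 1000 UMIs, B-like cells stood at 1.281. With each library clustered on its own, NK-like cells stood at 1.447, macrophage-like at 0.747, monocyte-like at -0.016, Ptprc-low at 0.053, naive-like T at 1.487 and CD8-effector-like cells at 0.485; the cause was not tested. Without doublet removal, monocyte-like cells stood at 0.729 and Ptprc-low cells at -0.434, and at Leiden resolution 2.0 these were 0.693 and -0.259.

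Equal weight for each class removes differences in the shares of named classes by its construction, but not in the mix within them. It also gives classes under 100 cells, such as plasma-like cells (48 treated and 12 PBS), the weight of large ones. A few cells can therefore drive its values. Under it 9 lists stood apart in the whole tumour, and Ccr7 was at -0.549, Cd3e at -0.690, Cd79a at -0.276, Cxcr5 at -0.095, Fcmr at -0.016, Ighg1 at -0.063, Il7r at -0.015, Jchain at -0.056, Ltb at -0.430 and Ubd at 0.194. Whole-tumour medians were then -0.057 for B cell genes, -0.202 for germinal centre and B cell activation, -0.060 for immunoglobulin and secretion, -0.284 for T cell genes, -0.016 for T cell activation, -0.101 for T cell exhaustion and -0.329 for follicular helper T cell genes. Dendritic cell maturation stood at -0.395, extracellular matrix at 0.346, angiogenesis at -0.034, the lymphotoxin and homing axis at -0.095 and tertiary lymphoid structure chemokines at 0.216.

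With each cell weighted equally, tertiary lymphoid structure chemokines stood at 0.095 and Cxcl12 at -0.174. After thinning to 1000 UMIs, these chemokines stood at 0.027, neutrophil and monocyte chemoattractants at -0.035 and immunogenic cell death and damage signals at -0.033 in the whole tumour. In classes, thinning gave Psmb8 at 0.207 in Ptprc-low, the epithelial-mesenchymal transition list at 0.263 in macrophage-like and glycolysis at 0.004 in conventional-dendritic-like cells. Without doublet removal Rsad2 stood at -0.368 in macrophage-like and Ccl7 at 0.055 in monocyte-like cells. With members of 10 UMIs or more, hypoxia stood at 0.149 in naive-like T and T cell exhaustion at -0.077 in Ptprc-low cells, and with members of 200 or more the epithelial-mesenchymal transition list stood at 0.291 in macrophage-like cells. In Ptprc-low cells the extracellular matrix list stood at 0.079 in cluster 3 and 0.016 in cluster 4, and the regulatory T cell list at -0.076 in cluster 3. The cause was not tested for any of these.

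Thinning lowers depth, drops cells under 1000 UMIs and evens out cell totals, and which of these matters was not tested. After it, 0 lists stood apart in naive-like T cells, 3 in CD8-effector-like, 3 in macrophage-like, 4 in monocyte-like, 0 in conventional-dendritic-like and 8 in Ptprc-low cells. In B-like cells 4 stood apart with equal cell weight, 6 without doublet removal, 3 with members of 10 UMIs or more and 0 with 200 or more. In naive-like T cells it was 1 under the stricter cell filter and 1 without the interferon-led sub-cluster. In CD8-effector-like cells it was 3 with members of 200 UMIs or more and 1 without the cycling sub-cluster. In conventional-dendritic-like cells it was 12 with members of 10 UMIs or more and 4 with 200 or more, and in Ptprc-low cluster 2 alone it was 13. The cause was not tested in the B-like, filter and single-cluster cases.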

Other observations

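The tests of B-like depth, of fewer Ptprc-low cells (on NK-like and then monocyte-like cells), of fibroblasts, of free RNA, of gene overlap, of all long genes alike, of the higher genes' span and of Hmga2 below were chosen only after the result was seen, the fibroblast and span readings were then made more cautious, and the genes of the next paragraph after their values were seen.

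Of the heat shock genes, which encode chaperones, Hspa1b had 708 treated and 2969 PBS UMIs in the whole tumour (log2 -1.78, -1.90 to -1.66), and Hsph1 stood at -0.59. The heat shock list stood apart in monocyte-like (-0.24) and CD8-effector-like cells (-0.27), where 3 of 11 and 3 of 8 members were lower by 1.5-fold, with Hsph1 at -1.15 and -1.05, but not in the whole tumour (-0.14) or the other 5 classes. The monocyte-like call ended after thinning (-0.24) and the CD8-effector-like call without the cycling sub-cluster. The glycolysis list stood apart as lower in the whole tumour (-0.18, 0 of 14 members by 1.5-fold), in CD8-effector-like (-0.31, 1 of 12), conventional-dendritic-like (-0.33, 1 of 11) and Ptprc-low cells (-0.12, 0 of 14). Its call ended after thinning in all 3 classes, at -0.20, 0.004 and -0.13, and with equal class weight in the whole tumour (-0.14).

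The larger share of B-like and naive-like T cells could come from depth, from fewer Ptprc-low cells recovered, from lymph node tissue in the sample, or from lymphocytes gathering after phototherapy. A first depth test, the PBS library thinned to 77.969% of its UMIs, gave a B-like ratio of 3.02 (2.68 to 3.41). It thinned barcode totals alone and kept each cell's class, so it could only show losses under the UMI minimum. That test was replaced after its value was seen by the median UMIs of B-like cells, 1155.5 treated against 1482 PBS. These medians argue against a greater loss of PBS B-like cells under the UMI minimum. They do not cover depth acting through the other cells counted. Among cells with at least 1000 UMIs, the B-like log2 ratio was 1.28 (1.09 to 1.48) against 1.59 among all kept cells. The share was thus still larger in the treated library, but depth as a part of the difference stays open. The upper bound of the NK-like ratio, 1.25, decides nothing, since with the libraries clustered apart the NK-like log2 interval (1.10 to 1.81) overlaps the B-like (1.42 to 1.77), but that of the monocyte-like ratio, 1.59, lies below the B-like lower bound of 2.67, as it does clustered apart (log2 -0.19 to 0.158), which argues against fewer Ptprc-low cells as the only cause. Summed Glycam1, Madcam1 and Cr2 were 1.87-fold higher (1.60 to 2.19). This lay between the limits set beforehand for these genes and Fdcsp, which is not among the listed genes. Most of the sum came from Cr2 with 396 and 246 UMIs, while Glycam1 had 6 and 18. Cr2 is also among the fixed B cell genes, so the sum cannot tell lymph node tissue from more B cells. Lymph node tissue therefore stays open, as do a part played by depth and an effect of the therapy.

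Ptprc-low cells lack the epithelial genes that a carcinoma line would carry, with Krt8 at 0.188 CPM, which could reflect genes that cannot be counted, dropped reads at overlaps, fibroblasts, or a line or state without an epithelial programme. Of the 10 epithelial markers, 2 reached 50 UMIs in another class while staying under 5 CPM here, namely Epcam (148 UMIs) and Cdh1 (160), so these can be counted, while for keratins and claudins it stays open. Another gene lies over the last 500 bases of 1 of the 10, which argues against reads dropped where genes overlap. Col1a2 was at 0.408% and Col1a1 at 1.37% of the fibroblast-like level but Col3a1 at 13.9% and Dcn at 59.5%, so fibroblasts stay open. These percentages pool clusters 2, 3 and 4. Cluster 2 matched fibroblasts best, with 5 of their markers met, too few for the naming rule. Its leading genes include Cilp, Tnc and Postn. Clusters 3 and 4 matched keratinocytes best, with 1 marker met in each. The fibroblast reading was not tested in single clusters. Hmga2 at 366 CPM bounds neither a different line nor a changed state, and both stay open.

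In all 7 compared classes alike, 16 genes were at least 1.3-fold higher and 3 lower in the treated library, of 5667 examined, where 1000 shuffles gave at most 1. They include Heph, at least 3.29-fold higher, Rpl9-ps6, Tecpr2, Adgrd1 and Ddah1, and the lower Selenbp1 (0.327 to 0.648) and Iqcn, and free RNA, shared pseudogene reads, unspliced RNA of long genes or a difference between the animals could each give this. At the median of the 19 genes, UMIs per cell were 17.3-fold higher in Ptprc-low than in B-like cells. This cannot decide on free RNA of 1 source, since a high ratio would also arise if Ptprc-low cells were that source. Ptprc-low cells also hold more UMIs in all, with medians of 29751 treated and 33569.5 PBS UMIs against 1155.5 and 1482 in B-like cells. By name, 5.26% of the genes are, or have, a pseudogene, but pseudogenes that are not listed or bear unrelated names were missed. Shared reads therefore stay open too. Median span lay at percentile 96.63 of random lists for all 19, which mixes directions and decides nothing, and at 98.95 for the 16 higher genes. The latter met the condition set for unspliced RNA of the long genes among them. Span is an indirect measure, however, and unspliced reads were not counted apart, so this cause is not shown. It would not cover Gm11361 and Rpl9-ps6, which span 607 and 714 bases, nor the 3 lower genes. The longest 10% of all genes reached a median of at most 0.11 in any class, a test added after that percentile was seen, which argues against a 1.3-fold shift of all long genes alike. In all 7 classes, however, that median lay above the one of the shortest 10%. The gap ran from -0.079 against -0.082 in macrophage-like to 0.111 against -0.092 in naive-like T cells. A smaller tilt with gene length therefore stays open, and a difference between animals was not tested.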
